A study of Rattus norvegicus with 4 samples.

How the data were processed

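Mast cells selected with AA4 from the pancreatic lymph nodes of DRlyp/lyp and DR+/+ BioBreeding rats were profiled on an Affymetrix rat genome array. Per the series' design text, RNA of 8 female animals was pooled per group, about 50 ng was amplified in 2 cycles, and each of the 2 pools was amplified independently for 2 arrays. Groups and replicate numbers were taken from the sample titles. The titles name the groups DP and DR, which were read here as DRlyp/lyp and DR+/+.

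The deposited values are intensity on a linear scale, 1 value per probe set and array. The program that made them and its scaling are not given in the sources used here. The 2% trimmed mean of the deposited values was 150.1 on each of the 4 arrays, and the values were kept as deposited. No detection calls were used, so the dimness of a probe set was judged from its signal. Probe sets at or below the floor made up 23.1% and 24.4% of the DRlyp/lyp arrays and 25.1% and 27.5% of the DR+/+ arrays.

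Of 31099 probe sets, 57 control sets were left out of the tests. Values were floored at the pooled 25th percentile, 6.8, and log2 transformed. Probe sets above the pooled median, 28.3, on at least 2 of the 4 arrays were tested, which left 16068. The difference, DRlyp/lyp minus DR+/+, was tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The fit had 2 residual degrees of freedom. Folds are on the floored scale. A gene below 28.3 on both arrays of a pool, a signal not shown to be above background, was given as at least the fold against 28.3, and log2 differences of such genes depend on the floor. Levels of different genes were not compared. Signals of different probe sets were set against each other only to choose a gene's brightest set, for the 3′ to 5′ difference, and in the closing test of brighter against dimmer sets of a gene.

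Gene symbols came from the platform's annotation of 2016. Of the probe sets that were not controls, 20826 had 1 gene symbol, 436 several and 9780 none in that table; no gene was named from a set with several. The Entrez numbers of 20758 were found in the RefSeq gene table of the GRCr8 assembly, which changed 0 symbols and was used for names only. The files name no genome build, so no coordinates are given. A gene was represented by its tested probe set with the highest mean log2 signal, which gave 9349 genes.

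The 36 gene lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined. The lists hold 950 genes, of which 772 were matched to a probe set with 1 symbol and 618 tested; the others were not analysed here. They cover mast cell markers, proteases, lipid mediators, IgE receptor signalling, inhibitory receptors, degranulation, cytokines, chemokines and their receptors, interferon, MHC class I and II, Gimap, apoptosis, early response, stress, NF-kB, cell cycle, matrix protease, ribosomal and metabolic genes, and markers of other cell types. Each list with at least 5 tested genes was compared with the other genes by limma's camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 33 lists. Named were the Gimap genes, the 10 largest called differences each way on the floored scale whose arrays did not overlap, up to 5 each way at the floor in 1 pool, up to 3 called genes each way per list (or the brightest member where none was called), and Kit, Fcer1a, Ms4a2, Cpa3 and Cma1. The examples given are from these 182 genes unless stated. Reg1a, Ins2, Gcg, Iapp, Clps, Sycn, Zg16, Cel and the genes of the lists added later were named after their values were seen.

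On simulated arrays with 200 of 16068 probe sets changed, the test recovered 16% of log2 changes of 0.5, 56% of 1, 82% of 2 and 96% of 3. Of 134 calls, 9 (6.72%) were false. More probe sets were called in the data (6302), so the recovered shares do not carry over to it. Noise was drawn independently for each probe set, so the simulation does not check the preset correlation. A simulated shift of 1 in the T cell list was called with the preset correlation (adjusted p = 1.72e-52) and not with an estimated one (adjusted p = 0.112).

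The 3′ to 5′ difference was the log2 signal of the 3′ minus the 5′ control probe set on each array, with no test. Hexokinase was left out because its signal did not exceed 15.8. The alternatives tried were quantile normalization, centring on the array median, no filter and a filter at the 75th percentile, a floor at the 10th percentile, an offset of 50, a block on the replicate number, leaving out each array, no intensity trend, a test against a 1.5-fold difference, a 2-fold minimum, the mean of a gene's probe sets and an estimated correlation in camera. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.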

Results

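Gene expression was measured in mast cells taken from the pancreatic lymph nodes of female BioBreeding rats at day 65. The cells were selected for AA4, an antibody that recognises gangliosides on the surface of rat mast cells. BioBreeding DRlyp/lyp rats carry the lyp mutation of Gimap5, lack most peripheral T cells and develop autoimmune diabetes, whereas DR+/+ rats carry the normal gene and are resistant. The comparison asked how mast cells in the lymph node that drains the pancreas differed between the diabetes-prone and the resistant rats. Genes of other cell types lay above the filter in both the DRlyp/lyp and the DR+/+ pool, such as Cd79b (463 and 1527) and Cd3g (1397 and 217). Kit lay below it. The share of mast cells in each pool is not known here, so no difference below can be assigned to mast cells alone. RNA of 8 animals was pooled per group, and each pool was amplified and hybridised in duplicate, which gave 4 arrays. Each value below is a mean ± SD over the 2 arrays of 1 pool, as signal in linear units. The p-values therefore measured the spread between amplifications and arrays and compared the 2 pools, not the strains. The number of arrays limits the precision, and no spread between animals can be had from them.

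Among the gene lists fixed beforehand, the DRlyp/lyp pool had higher signal of exocrine pancreas, T cell and cell cycle genes and lower signal of immediate-early, chemokine, interferon-stimulated and B cell genes than the DR+/+ pool. With an estimated correlation in camera these list calls were lost. Adjusted p was then 0.22 for the exocrine pancreas, T cell, cell cycle and immediate-early lists. It was 0.222 for interferon-stimulated genes, 0.337 for chemokines and 0.356 for B cell genes. That version also missed a simulated shift of 1 in the T cell list (adjusted p = 0.112), so a lost call does not show that a list is unshifted. Of 16068 probe sets tested, 3104 were higher and 3198 lower in the DRlyp/lyp pool at an adjusted p under 0.05 (limma). Of these, 975 were higher and 953 lower by at least 2-fold, 38 were higher by at least 10-fold, and 2 were lower by at least 10-fold. With a pool that was dim on both arrays set at the filter of 28.3, 789 and 820 were at least 2-fold and 27 and 1 at least 10-fold. On the floored scale, the 10 largest higher differences with 1 probe set per gene all fell on genes of pancreatic acinar products. They included Ctrb1, a chymotrypsinogen, at 1097 ± 123 against 11.9 ± 8.49 (at least 38.6-fold), Rnase1l2, a ribonuclease of the pancreatic family (50.3-fold), and Pnliprp1, a pancreatic lipase-related protein (at least 20-fold). Among the largest lower differences were Fosb, a subunit of the AP-1 transcription factor, at 236 ± 13.9 against 2317 ± 7.0 (9.83-fold lower), and Cxcl2, a chemokine that attracts neutrophils, at 25.6 ± 7.35 against 244 ± 40.2 (9.66-fold lower). Also lower were Cxcl1 (at least 3.38-fold lower), Cd24 (7.17-fold lower), the macrophage metalloelastase Mmp12 (5.24-fold lower) and Psap, the precursor of the lysosomal saposins (5.04-fold lower). In the pool with the lower signal, Ctrb1, Cela3b, Cpa1, Cpb1, Pnliprp1 and Cxcl1 lay below the filter on both arrays, so only a bound on their fold can be given. Which genes are among the 10 largest each way, and in what order, depends on the floor of 6.8 set before the log transformation. Without DRlyp/lyp replicate 1 the count was 3478 and without DRlyp/lyp replicate 2 it was 3767, against 6302 with all arrays. The 3′ to 5′ difference of beta-actin, a measure of the length of the amplified RNA, was larger in the DRlyp/lyp pool by 1.44 on the log2 scale, and with 1 pool per group it accompanied every difference given here. With each array centred on its median, 36.1% of calls were higher in the DRlyp/lyp pool, against 49.3% with the deposited scaling.

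Transcripts of digestive enzymes stood far higher in the DRlyp/lyp pool. Of 22 exocrine pancreas genes tested, 21 were higher and 0 were lower. The median log2 difference was 4.96, or 3.83 with the 15 genes that were dim in the DR+/+ pool at their bound. The camera adjusted p was 1.24e-21, or 0.22 with an estimated correlation. Those 15 genes passed the filter only through the DRlyp/lyp arrays, so their difference could only be higher. The count and the camera p-value are therefore partly set by the filter. Without a filter the list shift was still called. Trypsinogen Prss1 read 1519 ± 23.6 against 36.2 ± 4.81 (42.2-fold), amylase Amy2a3 1578 ± 52.1 against 34.5 ± 6.72 (46.2-fold), the elastase Cela2a 947 ± 39.5 against 25.9 ± 4.17 (36.7-fold) and procarboxypeptidase Cpb1 1091 ± 19.8 against 26.5 ± 0.424 (at least 38.5-fold). Both DR+/+ arrays lay at the floor for Prss3, Pnliprp2, Pla2g1b, Gp2 and Prss2, so these were higher by at least 10.8-, 8.54-, 7.02-, 6.25- and 4.49-fold. Reg1a, the member that did not pass the threshold, differed by 1.14 on the log2 scale. Of the islet hormone and beta cell genes, Ins1 alone passed the filter on dim probe sets and its difference of 1.06 was not past the threshold (adjusted p = 0.0562). Ins1 did pass it without DR+/+ replicate 1 (1.48, adjusted p = 0.0202) and with an offset of 50 in place of the floor (adjusted p = 0.0441). Ins2, Gcg and Iapp stayed below 6 on all 4 arrays.

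**Figure D1:**
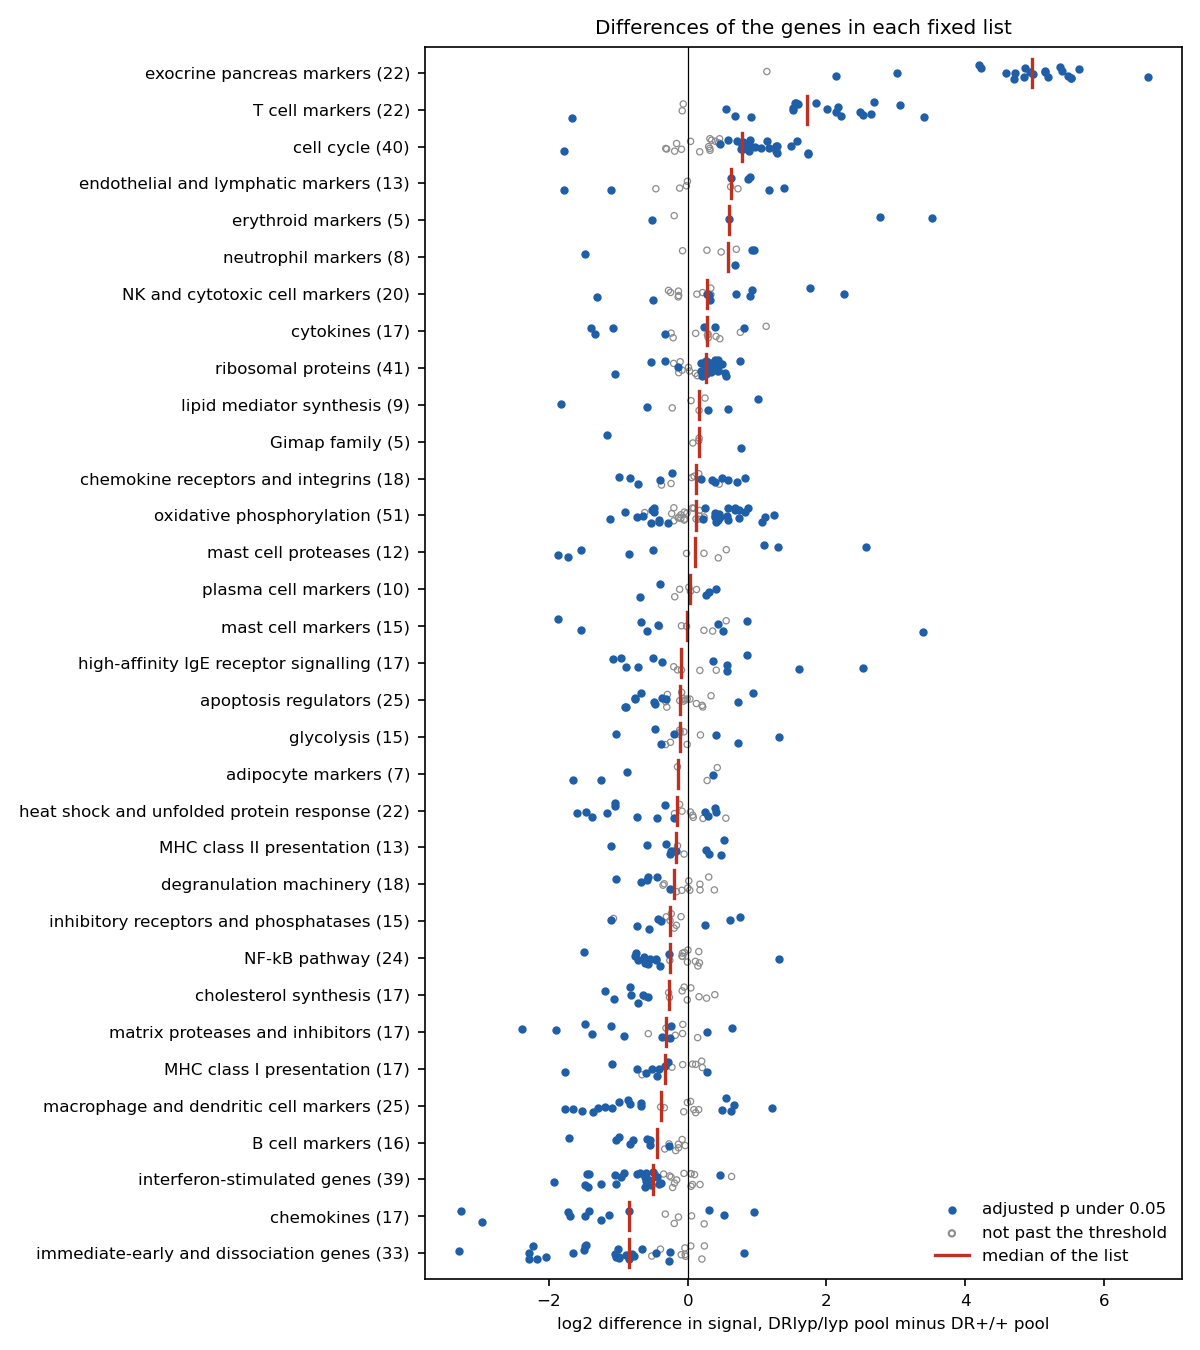
Log2 difference in signal, DRlyp/lyp pool minus DR+/+ pool, on the horizontal axis for each tested gene of the fixed lists with at least 5 tested genes, 1 row per list with the number tested in parentheses and the row's median as a vertical line. Filled points passed an adjusted p under 0.05; the exocrine pancreas list has its median at 4.96, the T cell list at 1.73 and the immediate-early list at -0.85.

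T cell genes were also higher in the DRlyp/lyp pool. Of 22 tested, 19 were higher and 1 lower, with a median log2 difference of 1.73, or 1.58 with 2 dim genes at their bound (camera adjusted p = 5.78e-12; adjusted p = 0.22 with an estimated correlation). Cd3e and Cd3g, chains of the T cell receptor complex, read 832 ± 71.4 against 78.1 ± 3.68 (10.6-fold) and 1397 ± 53 against 217 ± 8.63 (6.44-fold), and Bcl11b, a transcription factor of the T lineage, 801 ± 51.1 against 96.5 ± 5.44 (8.3-fold). Cd4 was the 1 lower member, at 15.7 ± 7.14 against 47 ± 4.67 (at least 1.66-fold lower). Both DRlyp/lyp arrays lay below the filter for Cd4, so it entered the test only through the DR+/+ pool. Its call was lost without DRlyp/lyp replicate 2 (log2 difference -1.18) and without DR+/+ replicate 2 (-1.56). Of 20 NK and cytotoxic cell genes 8 were higher and 2 lower (camera adjusted p = 0.146; adjusted p = 0.0413 with the mean of a gene's probe sets), with Klrc2, an NK receptor chain, at 324 ± 0.707 against 69.9 ± 21.1 (4.75-fold) and the cathepsin Ctsw at 98.8 ± 10.7 against 29 ± 2.12 (3.4-fold). Gzmb was lower by 1.41-fold, but another of its probe sets was higher and the call was lost with the mean of its probe sets (adjusted p = 0.917).

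B cell and macrophage genes went the other way. Of 16 B cell genes tested, 0 were higher and 9 lower, with a median log2 difference of -0.44 (camera adjusted p = 2.63e-05; adjusted p = 0.356 with an estimated correlation). Cd79b, a chain of the B cell receptor complex, read 463 ± 12.4 against 1527 ± 244 (3.28-fold lower), the tetraspanin Cd37 was 2.04-fold lower, and the follicular homing receptor Cxcr5 1.99-fold lower. Of 25 macrophage and dendritic cell genes 5 were higher and 12 lower, with a median of -0.39 (camera adjusted p = 0.020; adjusted p = 0.356 with an estimated correlation). The iron exporter Slc40a1 (178 ± 8.77 against 604 ± 8.63), the glycoprotein Gpnmb (601 ± 57.3 against 1892 ± 40.3) and the complement chain C1qb (311 ± 37.1 against 893 ± 83.7) were lower, while the lectin Clec10a (480.1 ± 38.3 against 209 ± 38.5) and the integrin chain Itgax (768 ± 56 against 499 ± 20.2) were higher. The shift of this list was not past the threshold without DR+/+ replicate 2 (adjusted p = 0.0627) or with the filter at the 75th percentile (adjusted p = 0.0579).

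Other cell type lists were not past the threshold of the list test. A missed threshold does not show that a list is unshifted. The median log2 difference was 0.60 for the erythroid and 0.58 for the neutrophil list, with few genes tested in each. Among erythroid genes, 3 of 5 were higher and 1 lower (camera adjusted p = 0.183): beta-globin Hbb read 1543 ± 74.2 against 135 ± 12.9 (11.5-fold), the haem synthesis enzyme Alas2 was at least 2.27-fold higher and the transferrin receptor Tfrc 1.43-fold lower. Of 13 endothelial and lymphatic genes 5 were higher and 2 lower, with a median of 0.62 (camera adjusted p = 0.52). The VEGF receptor Kdr, at 115 ± 27.6 against 388 ± 2.69, was among the 2 lower. Of 8 neutrophil genes 3 were higher and 1 lower (camera adjusted p = 0.13), with the ficolin Fcnb higher at 2098 ± 29.1 against 1081 ± 123. Of 10 plasma cell genes 3 were higher, among them Jchain (7469.5 ± 238 against 5637 ± 135, a call lost with the mean of its probe sets, adjusted p = 0.109), and 2 lower, among them the BAFF-family receptor Tnfrsf17 (369.5 ± 53.5 against 595 ± 3.39; camera adjusted p = 0.731). Of 7 adipocyte genes 1 was higher and 3 lower (camera adjusted p = 0.344), with the desaturase Scd lower at 111 ± 1.98 against 349.6 ± 33 and adipsin, Cfd, lower at 146 ± 17.1 against 351 ± 67. Too few fibroblast and eosinophil genes passed the filter for a list test. Of 4 fibroblast and reticular genes 2 were higher, fibronectin Fn1 (2379 ± 72.8 against 856 ± 92.1) and vimentin (3370.2 ± 45.5 against 2139.5 ± 217). Of 3 tested genes of the eosinophil list 2 were lower, including Adgre1 (438 ± 30.6 against 700.2 ± 66.5). With so few genes and no list test, a lower eosinophil signal is not shown.

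The mast cell genes themselves showed no common direction. The mast cell carboxypeptidase Cpa3 read 522 ± 8.63 against 444 ± 25.7 (log2 difference 0.23, adjusted p = 0.107), the chymase Cma1 287 ± 26.8 against 289.8 ± 21.8 (-0.02, adjusted p = 0.938) and Ms4a2, the beta chain of the high-affinity IgE receptor, 67.2 ± 3.32 against 72.3 ± 15.3 (-0.09, adjusted p = 0.815). Of 15 mast cell markers tested, 4 were higher and 5 lower, with a median of -0.02 (camera adjusted p = 0.833). The tryptases Tpsb2 and Tpsab1 were lower in the DRlyp/lyp pool, at 31.6 ± 4.03 against 91 ± 2.26 and 24.9 ± 7.0 against 89.9 ± 18.2. Il1rl1, the receptor for interleukin 33, was higher at 117 ± 4.31 against 11.2 ± 1.27 (at least 4.13-fold, since both DR+/+ arrays lay below the filter). Fcer1a, the alpha chain of the IgE receptor, was higher at 108 ± 0 against 62.8 ± 28.3 (adjusted p = 0.041), a call lost without DRlyp/lyp replicate 1 (adjusted p = 0.186), DRlyp/lyp replicate 2 (adjusted p = 0.185) or DR+/+ replicate 2 (adjusted p = 0.213). Kit, the stem cell factor receptor, stayed below the filter of 28.3 on all 4 arrays, with a highest value of 11.3.

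**Figure D2:**
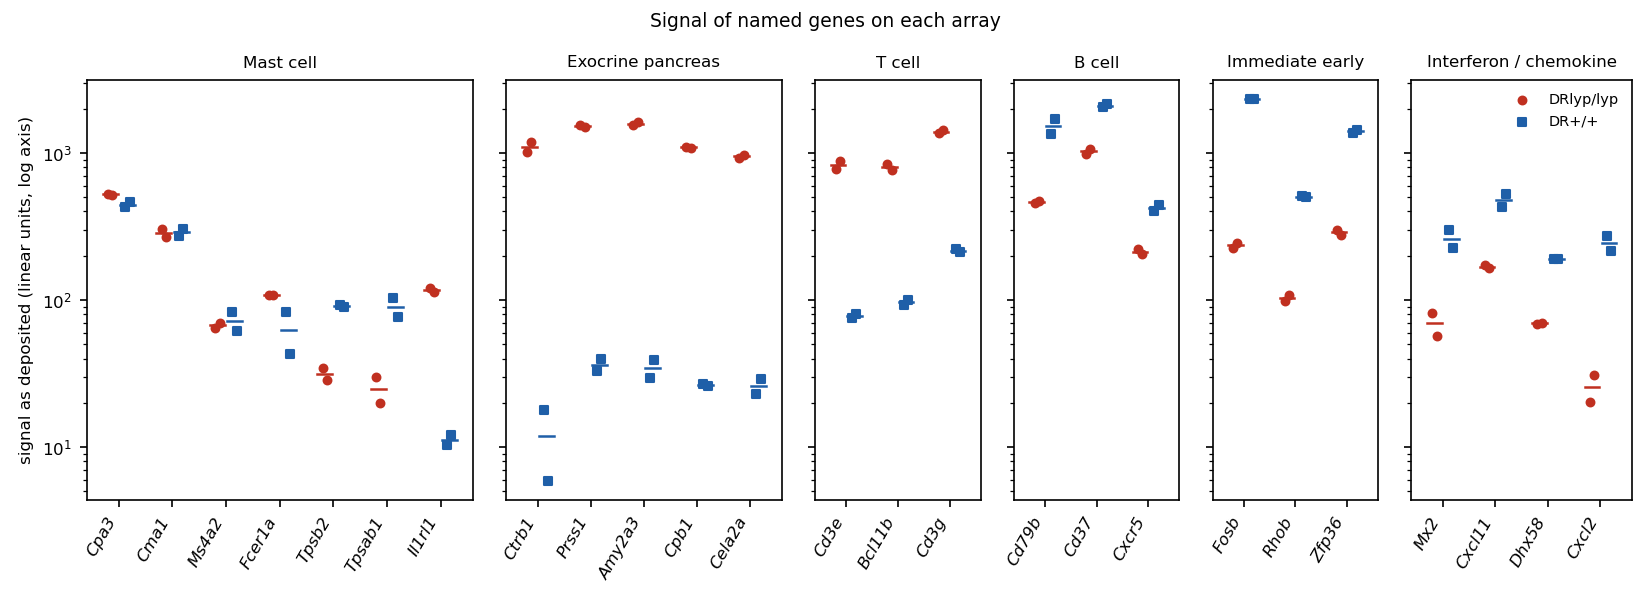
Signal as deposited on each of the 4 arrays for named genes, on a log axis in linear units, with circles for the 2 DRlyp/lyp arrays, squares for the 2 DR+/+ arrays and a line at each pool's mean. Cpa3 and Cma1 lie close together in both pools, while Prss1 lies at 1519 against 36.2 and Fosb at 236 against 2317.

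The lists of mast cell products and of the machinery that releases them were not past the threshold of the list test. Of 12 mast cell proteases 3 were higher and 5 lower (camera adjusted p = 0.965): Mcpt1 read 1633 ± 44.5 against 662 ± 9.55, Mcpt3 208 ± 27.2 against 97.2 ± 9.4 and Mcpt4 55.5 ± 7.42 against 8.2 ± 6.36, whereas Mcpt1l1 read 155 ± 74.3 against 483 ± 26. These proteases are near copies of one another, so signal of 1 probe set may include that of others. Mcpt4 lay below the filter on both DR+/+ arrays, so its signal there is not shown to be above background. Of 17 genes of IgE receptor signalling 6 were higher and 6 lower (camera adjusted p = 0.898). The phospholipase Plcg1 (361 ± 33.4 against 62.4 ± 3.75) and the adaptor Lat (265 ± 14.6 against 87.2 ± 1.77), which T cells also use, were higher, and the kinase Btk (474 ± 14.4 against 996 ± 2.19) and the phospholipase Plcg2 (273 ± 4.1 against 533 ± 22.7), which B cells also use, and the adaptor Grb2 (678 ± 132 against 1244 ± 14.8) were lower. Of 18 degranulation genes 0 were higher and 6 lower (camera adjusted p = 0.13), with the granule membrane protein Cd63 at 1844 ± 0.99 against 2940.2 ± 55.5. Of 9 genes of lipid mediator synthesis 3 were higher, including thromboxane synthase Tbxas1 (378 ± 9.12 against 187 ± 23.9), and 2 lower, including the prostaglandin-degrading Hpgd (239 ± 36.3 against 850.0 ± 121; camera adjusted p = 0.731). Of 15 inhibitory receptors and phosphatases 3 were higher and 5 lower (camera adjusted p = 0.146; adjusted p = 0.0266 without a filter), with the phosphatase Ptpn11 higher at 1212 ± 38 against 721 ± 85.3 and Ptpn6 lower at 1631 ± 31.8 against 2701 ± 163. With the mean of its probe sets Ptpn11 differed by 0.40 in place of 0.75 and its call was lost (adjusted p = 0.0968), and it was also lost without a filter (adjusted p = 0.0791). The median and mean of the mast cell marker, mast cell protease, IgE receptor signalling, lipid mediator, Gimap and plasma cell lists differed in sign.

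Gimap5, the gene of the lyp mutation, read 517 ± 2.47 against 466 ± 93.3 (log2 difference 0.16, adjusted p = 0.362). Without DR+/+ replicate 2 the difference was 0.37 and past the threshold (adjusted p = 0.0317). Where its probe set lies relative to the mutation was not known here, so this value checks neither the mutation nor the labels. Of the 5 Gimap genes tested, Gimap1 was higher at 475 ± 42.6 against 281 ± 44.6 and Gimap4 lower at 106 ± 11.2 against 237 ± 34, while Gimap6 (0.16) and Gimap7 (0.07) did not pass the threshold (camera adjusted p of the list = 0.731). Gimap7 passed it without DR+/+ replicate 2 (0.33, adjusted p = 0.0384).

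Immediate-early genes, which cells induce within minutes of stimulation and also on dissociation of tissue, were lower in the DRlyp/lyp pool. Of 33 tested, 1 was higher and 23 lower, with a median log2 difference of -0.85 (camera adjusted p = 7.72e-11; adjusted p = 0.22 with an estimated correlation). Beside Fosb, those lower included Rhob, a small GTPase, at 104 ± 6.86 against 505 ± 9.4 (4.88-fold lower), and Zfp36, which speeds the decay of cytokine transcripts, at 288 ± 16.6 against 1399.8 ± 33.8 (4.86-fold lower). The 1 higher member was Nr4a3 (1.76-fold), a call lost without DRlyp/lyp replicate 1 (adjusted p = 0.228), without DR+/+ replicate 2 (adjusted p = 0.0939) and with the mean of its probe sets (adjusted p = 0.69).

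Chemokine, NF-kB pathway and matrix protease genes were also lower as lists. Of 17 chemokines 3 were higher and 9 lower, with a median of -0.84 (camera adjusted p = 0.0196; adjusted p = 0.337 with an estimated correlation). Beside Cxcl2 and Cxcl1, platelet factor Pf4 was 3.29-fold lower, whereas Ccl17, a ligand of Ccr4, was higher at 414 ± 57.8 against 213 ± 18.3. Of 24 NF-kB pathway genes 1 was higher, the inhibitor Tnip1 (1397 ± 122 against 559.7 ± 37.1), and 12 were lower, including Irak3 (289 ± 7.85 against 813 ± 13.3), Birc3 (659 ± 20.4 against 1113 ± 78.6) and Ripk2 (146 ± 7.64 against 246 ± 9.9), with a list median of -0.26 (camera adjusted p = 0.0256; adjusted p = 0.337 with an estimated correlation). Of 17 cytokines 3 were higher and 4 lower (camera adjusted p = 0.779), with Il1a lower at 46.5 ± 9.97 against 121 ± 12.7 and Il15 lower at 58.5 ± 1.91 against 149.5 ± 39. Of 17 matrix proteases and inhibitors 2 were higher and 9 lower, with a median of -0.31 (camera adjusted p = 0.00297; adjusted p = 0.328 with an estimated correlation). Among those lower, Mmp12 and the lysosomal proteases Ctsd (453 ± 1.91 against 1693 ± 24.5) and Ctss (2.16-fold lower) are also made by macrophages, whose marker list had a median of -0.39 in the same comparison. The chemokine shift was not past the threshold without a filter (adjusted p = 0.20, median -0.07) or with the filter at the 75th percentile (adjusted p = 0.151), and the NF-kB shift was not with the latter (adjusted p = 0.102). Of 18 chemokine receptors and integrins 7 were higher, among them Itga6 (615 ± 53.5 against 347 ± 36.4), and 5 lower, among them Cxcr4 (2014 ± 14.8 against 3299 ± 5.3; camera adjusted p = 0.602).

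Interferon-stimulated genes were lower in the DRlyp/lyp pool. Of 39 tested, 1 was higher and 23 lower, with a median log2 difference of -0.50 (camera adjusted p = 3.20e-06; adjusted p = 0.222 with an estimated correlation). The antiviral GTPase Mx2 read 69.4 ± 17.4 against 261 ± 51.6 (3.79-fold lower), the chemokine Cxcl11 169 ± 4.45 against 476 ± 67.5 (2.8-fold lower) and the RNA sensor Dhx58 69.5 ± 0.778 against 190.2 ± 1.27 (2.74-fold lower), while Ifi35 was higher at 822 ± 10.4 against 594 ± 8.7. Cxcl9, Cxcl10 and Cxcl11 belong to the chemokine list as well. Of 17 genes of MHC class I presentation 1 was higher and 9 lower, with a median of -0.33 (camera adjusted p = 0.0209; adjusted p = 0.337 with an estimated correlation). The class I gene RT1-CE5 was 3.41-fold lower and the immunoproteasome subunit Psmb10 1.66-fold lower. B2m, the class I light chain, was the 1 higher member (1.21-fold), and its difference turned to -0.023 with quantile normalization. The class I shift was not past the threshold with the filter at the 75th percentile (adjusted p = 0.0579) or without an intensity trend (adjusted p = 0.0621). Of 13 genes of MHC class II presentation 4 were higher, including RT1-Da (9758 ± 559.6 against 6766 ± 398), and 7 lower, including Ctss (2413 ± 59.8 against 5217 ± 445; camera adjusted p = 0.52). For RT1-Ba and the class II regulator Ciita, which were higher by 0.48 and 0.31 on the log2 scale, other probe sets were lower.

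Cell cycle genes were higher in the DRlyp/lyp pool. Of 40 tested, 24 were higher and 1 lower, with a median log2 difference of 0.78 (camera adjusted p = 9.83e-06; adjusted p = 0.22 with an estimated correlation). The centromere protein Cenpf read 235 ± 29.5 against 70.5 ± 8.56 (3.33-fold), and cyclin A2, Ccna2, and the checkpoint kinase Bub1b were 3.32- and 2.97-fold higher, calls that were lost without DRlyp/lyp replicate 2 (adjusted p = 0.0837 and 0.084). The kinase Cdk2 was the 1 lower member, at 42.9 ± 13.3 against 148 ± 46.8. T cell genes were higher in the same pool, by a median of 1.73. Of 41 ribosomal protein genes 27 were higher and 4 lower, with a median of 0.26 (camera adjusted p = 1.48e-06; adjusted p = 0.22 with an estimated correlation). Rpl37a differed most among those higher (8494 ± 138 against 5016 ± 220.0) and Rpl24 most among those lower (1702 ± 144 against 3517 ± 16.1). With quantile normalization the ribosomal median was 0.03 and the shift was not past the threshold (adjusted p = 0.969).

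Metabolic and stress lists were not past the threshold of the list test. Of 51 genes of oxidative phosphorylation 21 were higher, among them Cox4i1 (2997 ± 119 against 1272 ± 81.5), and 11 lower, among them Uqcrfs1 (542 ± 9.69 against 1175 ± 3.54; camera adjusted p = 0.146). Of 15 glycolysis genes 3 were higher, including the glucose transporter Slc2a3 (167 ± 14.9 against 66.8 ± 4.17), and 4 lower, including Pfkfb3 (126 ± 12.2 against 257 ± 5.02; camera adjusted p = 0.685). Of 17 cholesterol synthesis genes 0 were higher and 7 lower (camera adjusted p = 0.067), including squalene epoxidase Sqle (66.2 ± 4.67 against 152 ± 25.9). Of 22 heat shock and unfolded protein response genes 4 were higher, including the chaperone Hspa5 (6446 ± 62.4 against 4889 ± 187), and 10 lower, including the transcription factor Atf4 (969.5 ± 2.9 against 2691 ± 105) and the disulfide isomerase Pdia4 (878 ± 59.8 against 2652 ± 362; camera adjusted p = 0.0719). Of 25 apoptosis regulators 2 were higher, including Bcl2l11 (1048 ± 52 against 636 ± 70.1), and 9 lower, including Casp4 (259.6 ± 7.0 against 489 ± 33.9; camera adjusted p = 0.167). The cholesterol list passed the threshold without a filter, without DR+/+ replicate 1 and without an intensity trend, with adjusted p of 0.0195, 0.0347 and 0.0494. The heat shock list passed it with quantile normalization, with centring on the median, without DRlyp/lyp replicate 1 and with the mean of a gene's probe sets, with adjusted p of 0.0352, 0.0121, 0.033 and 0.00959.

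Over the 36 lists, 383 of 618 genes tested were past the threshold over all probe sets tested, 192 higher and 191 lower. Adjusted over the list alone, the counts were 22 higher and 0 lower for the exocrine list, 19 higher and 1 lower for the T cell list, 1 higher and 24 lower for the immediate-early list, 1 higher and 24 lower for the interferon list and 25 higher and 2 lower for the cell cycle list. Of the 33 lists with at least 5 tested genes, 4 were shifted higher and 8 lower. With an estimated correlation limma's camera called 0 lists, and 6 had an unadjusted p under 0.05. That version of the test works with the 2 residual degrees of freedom of the 4 arrays.

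The signal of control transcripts fell off more steeply from the 3′ to the 5′ end in the DRlyp/lyp pool. For beta-actin the 3′ probe set exceeded the 5′ set by 4.49 ± 0.0868 on the log2 scale in the DRlyp/lyp pool and by 3.05 ± 0.0594 in the DR+/+ pool, and for GAPDH by 2.46 ± 0.0372 and 1.65 ± 0.118. The 4 poly-A control transcripts that are added to the RNA showed the same sign, with differences between the pools from 0.19 for Thr to 0.91 for Phe. The 4 hybridisation controls, which are added after amplification, ranged from -0.21 to 0.16. Their signal was higher in the DRlyp/lyp pool at both ends, by 0.36 to 0.52 on the log2 scale at the 3′ end and by 0.36 to 0.64 at the 5′ end. If equal amounts were added, which the sources used here do not state, the scaling raised the DRlyp/lyp arrays by about that much. The balance of 3104 higher and 3198 lower probe sets and the direction of small differences, such as the ribosomal median of 0.26, therefore depend on the scaling. Beta-actin itself was lower in the DRlyp/lyp pool with both probe sets, with log2 differences of -1.33 at the 3′ end and -2.77 at the 5′ end.

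**Figure D3:**
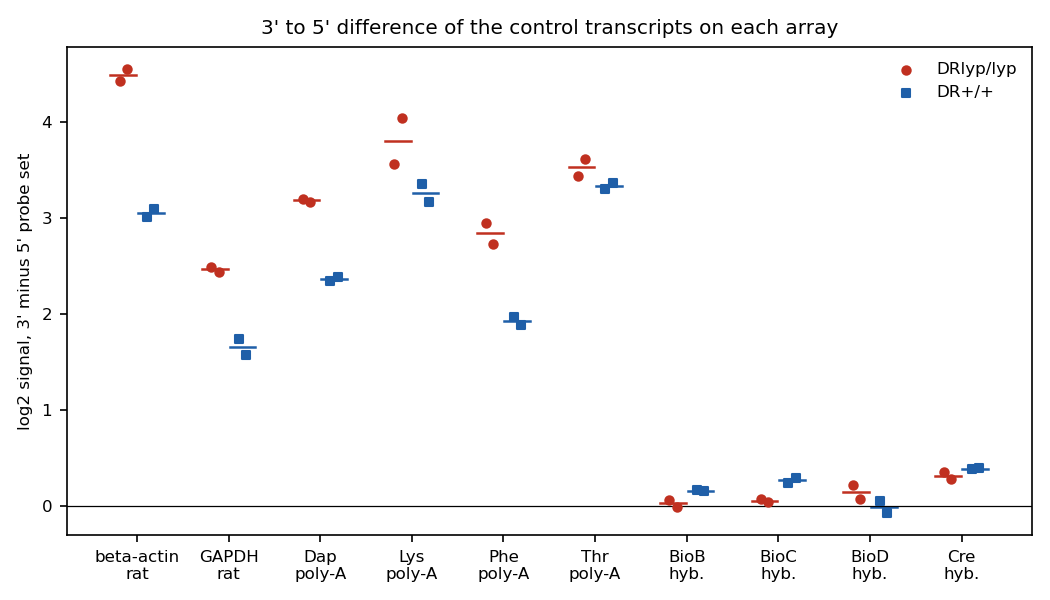
Log2 signal of the 3′ minus the 5′ probe set of control transcripts on the vertical axis, with circles for the 2 DRlyp/lyp arrays, squares for the 2 DR+/+ arrays and a line at each pool's mean. The circles lie above the squares for beta-actin, GAPDH and the 4 poly-A controls, and close to them for the 4 hybridisation controls.

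The 2 arrays of a pool agreed closely. Over the probe sets tested, Pearson's r across probe sets was 0.983 between the DRlyp/lyp arrays and 0.975 between the DR+/+ arrays, against 0.908 to 0.916 between arrays of different pools. The SD of the log2 differences was 0.34 and 0.42 within pools and 0.76 to 0.79 between them. Probe sets are not independent replicates. Among the 472 genes with several called probe sets, 158 (33.5%) had calls in both directions, so a single gene's direction depended on the probe set used. Among the 182 named genes these were Ciita, Edem1, Gzmb, RT1-Ba and Sdhd. Of the 175 named genes past the threshold, 133 kept their call when any 1 array was left out, and 65 kept it under each setting run for that gene other than the replicate block. The 1.5-fold test and the 2-fold minimum were not run for single genes, and a gene that the filter at the 75th percentile left out has no value there. With the mean of a gene's probe sets the log2 difference was 2.13 in place of 3.41 for Cd3e, 0.43 in place of 0.76 for Gimap1, -1.10 in place of -1.77 for Slc40a1, -1.27 in place of -0.71 for Cxcr4, -1.83 in place of -0.99 for Cxcr5 and -0.94 in place of -0.51 for Tfrc.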

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

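The tests kept the total of 6302 probe sets (3104 higher, 3198 lower) within 1.5 times except as follows. A 2-fold minimum left 1928 (975 and 953), no filter 1671 (844 and 827), no intensity trend 4057 (1932 and 2125), and a test against a 1.5-fold difference 958 (480 and 478). Leaving out 1 array gave 3478 to 5800 (1595 to 2987 higher, 1883 to 2813 lower), where the lone array of a pool is assumed to vary like the other pool's; the lowest counts came without DRlyp/lyp replicate 1 (3478) and 2 (3767). Against 383 list genes called, 137 were called without a filter and 243 without an intensity trend. Centring on the median moved the median difference of all probe sets tested to -0.11, and 5415 calls were shared with the deposited scaling; the list test, which is relative to the other genes, called 13 lists. With an estimated correlation 0 lists were called. B2m turned to -0.023 with quantile normalization (the cause was not tested). With the mean of a gene's probe sets Ciita turned to -0.11, Edem1 to -0.0072 and RT1-Ba to -0.22, since each mean joins sets called in opposite directions. The 3′ to 5′ difference of beta-actin was 1.26 with quantile normalization and 1.03 with an offset of 50, against 1.44. The mean r within pools was 0.987 with the filter at the 75th percentile and 0.990 with the offset, against 0.979. Over all settings 2060 values of named genes stayed on their side of the threshold, 252 fell short of it, 5 newly passed it and 4 reversed; for lists 425 stayed, 21 fell short and 12 newly passed. Of the 12 lists shifted, 7 (exocrine pancreas, T cell, B cell, cell cycle, immediate-early, interferon and matrix protease) kept their call under each setting run for lists other than the block and the estimated correlation. The replicate numbers showed no shared effect on signal, since the correlation of their deviations between the pools was 0.04. Whether arrays with the same number were handled together is not known here. A replicate block, with 1 residual degree of freedom, called 7044 probe sets (3492 and 3552), of which 6301 were shared. The block also passed Ins1 (adjusted p = 0.0344) and called 14 lists, losing NF-kB and adding heat shock, oxidative phosphorylation and erythroid genes. Signal over background limits what could be seen, since dim probe sets were left out. In the simulation 16% of log2 changes of 0.5 were recovered. That share does not carry over to the data, where more probe sets were called.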

Other observations

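The lysosome, type 2 and regulatory lymphocyte, and actin lists below, and the tests of cross-hybridisation and of a lower mast cell share, were chosen after the results were seen. Of 48 lysosomal genes tested, 6 were higher and 23 lower in the DRlyp/lyp pool, with a median log2 difference of -0.25 (camera adjusted p = 1.88e-04; adjusted p = 0.219 with an estimated correlation). The proton pump accessory subunit Atp6ap1 read 262 ± 4.38 against 1113 ± 11.7, the ceramidase Asah1 168 ± 1.13 against 543 ± 95.2 and the sialidase Neu1 29.2 ± 14.4 against 63.1 ± 13.2. Psap, Ctsd and Atp6ap1 had been seen to differ before the list was made, so it is not independent evidence of the direction. Among the lysosomal genes that were higher were Cd68 (2540 ± 39.1 against 1796 ± 70.8) and Gm2a (1621 ± 89.0 against 1010 ± 57.6). Macrophages are rich in lysosomes, and the macrophage and dendritic cell list had a median of -0.39, with 12 of 25 lower and 5 higher. A link between the 2 lists was not tested. Of 14 type 2 and regulatory lymphocyte genes 10 were higher and 0 lower, with a median of 1.58, or 0.89 with dim genes at their bound (camera adjusted p = 1.21e-04; adjusted p = 0.221 with an estimated correlation). Gata3, a transcription factor of type 2 lymphocytes, read 440.5 ± 23.3 against 78 ± 9.9, the death receptor Tnfrsf25 861 ± 68.7 against 161 ± 34.7, Ikzf2 129 ± 6.79 against 30.1 ± 6.29 and the interleukin 9 receptor Il9r 112 ± 18.5 against 31.2 ± 14.1. Gata3, Il1rl1, Tnfrsf25 and Icos had been seen to differ before this list was made, so it too is not independent evidence of the direction. Il1rl1, Icos and Klrg1 also belong to the mast cell, T cell and NK lists, and Il2ra and Tnfrsf4 to the second T cell list used below. Il1rl1, Il2ra and Tnfrsf4 lay below the filter on both DR+/+ arrays, so they entered the test only through the DRlyp/lyp pool. The T cell list moved the same way (19 of 22 higher, median 1.73), so a shift particular to type 2 or regulatory lymphocytes is not shown. Of 43 genes of the actin cytoskeleton 14 were higher and 18 lower (camera adjusted p = 0.277), with profilin Pfn1 lower at 669.8 ± 36.8 against 2511 ± 139. Eif2s3y, which is named for the Y chromosome, read 3.6 ± 1.84 against 58.6 ± 37.5 although the animals were female by the labels, and was at least 1.85-fold lower in the DRlyp/lyp pool; whether its probe set also reads the X-linked copy is not known here.

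The exocrine pancreas genes were higher in the DRlyp/lyp pool although the cells were selected for AA4. Cross-hybridisation among related proteases would not raise acinar genes with no near copy. Clps, Gp2, Sycn, Pla2g1b, Zg16 and Cel, 6 such genes, were each called higher, by at least 6.25-fold for Gp2 to at least 18.7-fold for Clps. They were picked with the results in hand, so their count is not a separate test. Clps, Gp2 and Pla2g1b among them were dim on both DR+/+ arrays and entered the test only through the DRlyp/lyp pool. Whether cross-hybridisation adds to the signal of the proteases was not tested. In a second list of 33 acinar and pancreatic epithelial genes, 10 passed the filter and 1 of these (10%; exact 95% interval 0.253% to 44.5%) was called higher, against 20.9% of all genes tested (Fisher's exact p = 0.699), and 2 were lower. The member called higher was Aqp12a, at 56.6 ± 3.11 against 28.65 ± 15.3. The median of the second list was 0.14 (camera adjusted p = 0.957). Its interval holds the share of all genes, so it cannot decide on RNA of acinar tissue carried over with the lymph node. Carry-over of acinar RNA, which may account for the pattern, the handling of each pool and the strain cannot be told apart with 1 pool per group.

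The T cell genes were higher in the DRlyp/lyp pool although DRlyp/lyp rats have few T cells. A lower mast cell share that raised every other cell type alike is argued against by the B cell genes, whose median was -0.44. The T cell median exceeded it by 2.16 on the log2 scale (22 and 16 genes, two-sided permutation p = 0.00064). Both medians were known when this comparison was chosen, so it is not an independent test. The permutation treated genes as independent, so its p-value measures no spread between pools or animals. A larger share of T cells among the selected cells is consistent with a second list of T cell genes whose values had not been looked at, of which 9 of 20 (45%; exact 95% interval 23.1% to 68.5%) were called higher, against 20.9% of all genes tested (Fisher's exact p = 0.0224). The second list shifted by a median of 0.27 and not past the threshold of the list test (camera adjusted p = 0.145), and 3 of its genes were lower. Il2ra, Inpp4b and Tnfrsf4, among those higher, lay below the filter on both DR+/+ arrays. They entered the test only through the DRlyp/lyp pool, where they were higher. Fisher's test also treated genes as independent, so its p-value measures no spread between pools or animals. The evidence is therefore weak. The AA4 selection should remove T cells; a difference of the strains in the cells that pass it stays open as untested, as does an exchange of the labels of the 2 pools, which would put the higher T cell signal in the strain that has T cells.

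Probe sets of 1 gene were called in opposite directions for 158 of 472 genes. Noise of dim probe sets is argued against by the 172 genes whose called sets all exceeded the 75th percentile of signal, of which 62 (36.0%; exact 95% interval 28.9% to 43.7%) had opposite calls. A trend of the difference with brightness over all probe sets is argued against as the whole cause, since after its removal the brightest set of a gene still had the higher difference than the dimmest in 66.3% of 2106 genes (exact 95% interval 64.2% to 68.3%). Shorter amplified products in the DRlyp/lyp pool may account for part of it. The brightest set had the higher difference in 64.2% of the genes (1351 of 2106, two-sided binomial p = 6.05e-39). In 124 of the 158 genes called both ways the brightest called set was the higher one. The binomial test treated genes as independent, so its p-value measures no spread between amplifications, pools or animals. That brighter sets lie nearer the 3′ end is assumed and was seen here only in the control transcripts. Whether the pools also differ in transcript ends was not tested.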
